A study of Homo sapiens with 27 samples.

How the data were processed

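RNA was measured in 27 libraries of 3 human acute myeloid leukaemia cell lines. Each line had 9 libraries in 3 groups of 3 replicates: a scramble shRNA, CARM1 hairpin 1 and CARM1 hairpin 2. Per the labels' protocols, RNA was taken 3 days after shRNA delivery with Trizol and RNeasy columns. Libraries were made with the TruSeq Total Stranded kit after Ribo-Zero depletion of ribosomal RNA. Per the submitters' processing notes, reads were aligned with STAR 2.5.3 to GRCh38.p7 and counted with RSEM, whose version was not given. The deposited table holds RSEM expected counts for 57992 genes in 27 columns, without normalization for depth or length. Of its non-zero values, 30.39% were not whole numbers (tolerance 1e-09), as RSEM shares reads that fit several genes. Counts of genes with near-identical copies, such as histone and some ribosomal protein genes, are for that reason uncertain. The kit is stranded, but the strand setting of the counting was not stated, so genes that overlap on opposite strands may share reads.

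Every column was matched to a sample by its label, and no column was left over. Totals ranged from 25063577 to 53291599 expected counts per library. Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with the quasi-likelihood F-test. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Fold changes are log2 with the standard error of the fit, and log2 CPM, counts scaled to library size, used a prior count of 2. Gene positions came from GENCODE 29, which held 57388 of the gene identifiers. A count of 0 allows up to 3 counts, and such limits cover counting error only.

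The comparisons were fixed before the data were examined. In each line, the 6 CARM1 knockdown libraries were compared with the 3 scramble libraries in a fit of that line's 9 libraries. All 18 knockdown libraries were compared with all 9 scramble libraries with line as a term. Each hairpin was compared with scramble and with the other hairpin in each line. The knockdown effect was compared between each pair of lines by an interaction term in a fit of all 27 libraries. No label states whether replicates were separate cultures, infections or portions of the same culture. The p-values therefore measure only the spread between these samples. Scramble replicates 1 and 3 of SKNO1 were closer to each other (chi-square per gene 7.75, after scaling to depth) than any other pair of replicates (lowest 23.2). If they were portions of the same culture, the p-values of SKNO1 could be too small.

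A total of 29 gene lists, written from general knowledge, were fixed with the comparisons. Each list was described by its genes past the threshold over all genes and adjusted over the list alone. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01. Each was tested again with the correlation estimated from the data and with fry. Genes were named by a fixed rule. CARM1 and the other arginine methyltransferases were always named. In each comparison of knockdown with scramble, up to 10 genes per direction with the largest fold changes were taken from genes past the threshold with mean log2 CPM of at least 2. They also had to have the same sign for both hairpins, and every knockdown library on the same side of every scramble library or the same sign in all 3 lines. Up to 3 genes per direction were taken for differences between hairpins or lines. Up to 3 members of a list in its main direction and 1 in the other were taken by smallest p. The hairpins of each line were compared with the same controls, so the correlation this makes between them was simulated 20 times on data without change.

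The test was checked on simulated data in which 100 genes were changed 2-fold or 4-fold. Of genes changed 2-fold, 33% were recovered in MOLM13, 56% in MV411, 49% in SKNO1 and 70% in the 3 lines combined. Of genes changed 4-fold, the shares were 70%, 80%, 83% and 87%. In these comparisons, which pool the hairpins, the simulation gave both hairpins the same change and used the spread within each group. It left out the difference between hairpins seen in MV411 and SKNO1, so the shares for those lines and for the lines combined can be too high. Of genes changed 2-fold, 13% to 36% were recovered for a hairpin against scramble, 14%, 28% and 28% between the hairpins of MOLM13, MV411 and SKNO1, and 10%, 11% and 6% in the interactions of MOLM13 with MV411, MOLM13 with SKNO1 and MV411 with SKNO1. Of genes changed 4-fold the shares were 61% to 85%, then 63%, 78% and 88%, and 56%, 56% and 53%. In the simulated MOLM13 comparison, unchanged genes made up 27.7% of the calls of DESeq2 and 10.5% of those of limma-voom. These tools were simulated for MOLM13 only. Each comparison was simulated once, with spreads estimated by edgeR, which can favour edgeR. By edgeR they made up 8.8%, 2.9%, 5.0% and 2.5% of the calls in the comparisons of knockdown with scramble in MOLM13, MV411, SKNO1 and the lines combined. In the simulated interactions they made up 34.0% of calls for MOLM13 against MV411, 30.9% for MOLM13 against SKNO1 and 7.8% for MV411 against SKNO1. Camera called the list that had been changed, and 0 unchanged lists, in each of the 4 comparisons of knockdown with scramble. The simulated genes varied independently of each other, so this does not check camera on lists whose genes vary together. Over other splits of the real libraries camera called a median of 12 lists in MOLM13, 11 in MV411, 9 in SKNO1 and 11 in the lines combined.

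Alternatives tried were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, replicate number as a block, each library or replicate number left out, and a fit over all 27 libraries. Others were hairpins as separate groups or alone, each line left out of the combined comparison, no line term, and only the libraries compared. Removal of abundant structured RNAs, each hairpin alone in the interactions and the alternatives for overlaps were added after the data were examined. Library measures were compared by two-sided exact permutation tests over the 84 splits of 9 libraries, adjusted over 15 tests. Splicing, transcript isoforms and reads of the constructs were not analysed here. Some genes that the naming rule selects are not reported here.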

Results

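RNA was profiled in 3 acute myeloid leukaemia lines after knockdown of CARM1, an arginine methyltransferase (also called PRMT4) that modifies histone H3 and acts as a transcriptional coactivator. MOLM13 and MV411 are monocytic lines with a KMT2A rearrangement and an internal tandem duplication in FLT3. SKNO1 carries the RUNX1-RUNX1T1 fusion and was grown with 10 ng/mL GM-CSF. Each line had 3 libraries with a scramble hairpin, 3 with CARM1 hairpin 1 and 3 with CARM1 hairpin 2, collected 3 days after shRNA delivery. Totals ranged from 29004790 to 53291599 expected counts in the 9 libraries of MOLM13, from 25063577 to 39718356 in those of MV411 and from 32392863 to 40389063 in those of SKNO1. Over all 27 libraries, the first principal component held 57.11% of the variance and parted SKNO1 from the other lines. The second held 22.37% and parted MOLM13 from MV411.

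The share of counts taken by abundant structured RNAs differed between the groups. Mitochondrial rRNA made up 26.2% ± 1.46 of counts in MV411 scramble libraries (SD, n = 3) and 31.8% ± 1.95 in knockdown libraries (n = 6; exact permutation p = 0.0119, adjusted p = 0.0357 over 15 tests). In MOLM13 the shares were 24.9% ± 1.82 and 28.2% ± 1.86 (exact permutation p = 0.0357, adjusted p = 0.0893). In SKNO1 they were 0.0913% ± 0.0152 and 0.173% ± 0.136 (exact permutation p = 0.393). The RNAs of 7SL, 7SK, RNase P and RMRP took 18.6% ± 1.14 in SKNO1 scramble libraries and 24.9% ± 2.00 in knockdown libraries (exact permutation p = 0.0119, adjusted p = 0.0357). They took 12.4% ± 1.13 and 17.9% ± 3.10 in MOLM13 (exact permutation p = 0.0476, adjusted p = 0.102), and 12% ± 0.986 and 13.9% ± 1.63 in MV411 (exact permutation p = 0.131). Mitochondrial mRNA took 0.923% ± 0.133 and 0.754% ± 0.153 of counts in MOLM13, 0.696% ± 0.0102 and 0.612% ± 0.0882 in MV411, and 0.696% ± 0.0979 and 0.856% ± 0.162 in SKNO1 (exact permutation p = 0.155, 0.214 and 0.167). In MV411 it was 0.532% ± 0.012 with hairpin 1 and 0.693% ± 0.007 with hairpin 2 (SD, n = 3 each), and the structured RNAs took 15.011% ± 0.887 and 12.811% ± 1.494. The library totals did not differ detectably between knockdown and scramble in any line, with exact permutation p-values of 0.476, 0.774 and 0.952.

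CARM1 (ENSG00000142453, GRCh38 chromosome 19, 10871513 to 10923070, plus strand) was lower in each of the 18 knockdown libraries than in every scramble library of its line. In MOLM13 it went from 24.5 ± 4.15 CPM in 3 scramble libraries to 4.37 ± 1.31 in 6 knockdown libraries (SD; exact permutation p = 0.0119). In MV411 it went from 23.3 ± 0.622 to 4.56 ± 1.74 CPM, and in SKNO1 from 17.7 ± 1.95 to 5.15 ± 2.81 CPM, with the same exact permutation p of 0.0119. That p is the smallest the 84 splits allow, and it was 0.0357 after adjustment over 15 tests in each line. The CARM1 RNA left in MOLM13 was 19.4% ± 6.76 with hairpin 1 and 16.3% ± 4.39 with hairpin 2 (SD, n = 3 each). It was 26.2% ± 1.17 and 13.0% ± 2.70 in MV411, and 42.5% ± 9.18 and 15.6% ± 0.502 in SKNO1. CARM1 was higher with hairpin 1 than with hairpin 2 in MV411 (log2 fold change 1.02 ± 0.18, SE; adjusted p = 0.0046) and in SKNO1 (1.45 ± 0.20; adjusted p = 0.00096). In MOLM13 the difference of 0.22 ± 0.30 did not pass (adjusted p = 1).

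**Figure D1:**
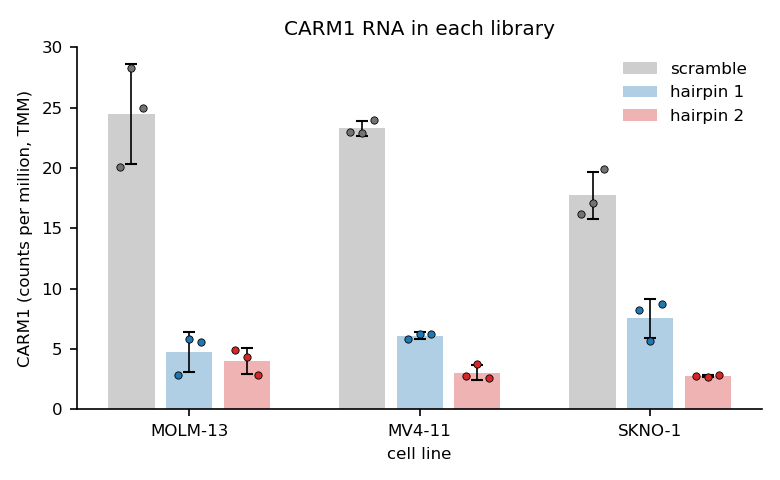
CARM1 in CPM (counts scaled to library size by TMM) in each of the 27 libraries, by cell line and hairpin. In every line the 6 knockdown points lie below the 3 scramble points, and in SKNO1 the hairpin 1 libraries kept 42.5% of the scramble level against 15.6% with hairpin 2.

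Some other arginine methyltransferases fell with CARM1 in MOLM13 and with hairpin 2 in MV411. In MOLM13, PRMT1, the main asymmetric enzyme, fell by 0.46 ± 0.11 (adjusted p = 0.018), and PRMT5, the main symmetric enzyme, fell by 0.51 ± 0.14 (adjusted p = 0.027). PRMT3 (-0.65 ± 0.20, adjusted p = 0.052), PRMT6, PRMT2, PRMT7 and PRMT9 did not pass there. Adjusted over the list alone, 4 of the 7 tested members were lower in MOLM13. None of the 7 passed in MV411, in SKNO1 or in the combined comparison by edgeR, over all genes or adjusted over the list alone. With hairpin 2 in MV411, PRMT1 (-0.50 ± 0.13, adjusted p = 0.02), PRMT3 (-0.72 ± 0.19, 0.021), PRMT5 (-0.51 ± 0.15, 0.034) and PRMT7 (-0.61 ± 0.16, 0.021) fell.

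The comparison of knockdown with scramble in MOLM13 asked what CARM1 loss changes in that line. Genes of DNA replication and of mitosis fell together. MCM4, MCM6 and MCM2, subunits of the replicative helicase, fell by 2.14 ± 0.12, 2.09 ± 0.13 and 2.01 ± 0.13 (SE; adjusted p = 2.1e-05, 2.2e-05 and 2.2e-05). CDC45, which activates that helicase, fell by 2.48 ± 0.25 (adjusted p = 0.00015), and the PCNA clamp partner KIAA0101 by 2.58 ± 0.46 (0.0039). Of 49 tested genes of E2F and DNA replication, 48 were lower and 0 higher over all genes, and 49 were lower adjusted over the list alone (median -1.65, camera adjusted p = 2.68e-47). This was the list call of MOLM13 that held with an estimated correlation (adjusted p = 0.00588). Of 38 mitosis genes, 37 were lower, and 38 adjusted over the list alone (median -1.96, camera adjusted p = 7.95e-40; adjusted p = 0.152 with an estimated correlation). CDC20, which starts anaphase, fell by 2.01 ± 0.15 (3.5e-05), the checkpoint kinase BUB1 by 1.90 ± 0.14 (3.5e-05) and the kinesin KIF2C by 2.56 ± 0.29 (0.00031). Replication-dependent histones were lower in 47 of 52, and in 48 adjusted over the list alone (median -1.78, camera adjusted p = 1.87e-24; adjusted p = 0.284 with an estimated correlation). Scramble replicate 1 stood low on the histones, with a mean log2 difference from the scramble mean of -0.85 against 0.255 and 0.595. The highest knockdown library was at -1.238. HIST1H1D fell by 2.68 ± 0.48 (0.0039; log2 fold change -1.659 without scramble replicate 3) and HIST1H2BJ by 2.59 ± 0.35 (0.00087), although counts of single histone genes are uncertain because their copies are alike.

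Genes of mature myeloid cells and of inflammation rose in MOLM13. CD14, the monocyte co-receptor for endotoxin, rose by 4.85 ± 0.89 (adjusted p = 0.0046) and the monocyte factor KLF4 by 1.42 ± 0.22 (0.0019). C3, the central complement protein, rose by 4.34 ± 0.57 (0.00071), the macrophage protease gene ADAMDEC1 by 4.06 ± 0.53 (0.00069) and ALOX5, which makes leukotrienes, by 2.62 ± 0.43 (0.0024). FCAR, the myeloid IgA receptor, rose by 2.81 ± 0.55 (0.0062), and the lipid carrier APOE by 2.67 ± 0.73 (0.031). Of 37 mature myeloid genes, 15 were higher and 0 lower, and 22 were higher adjusted over the list alone (median 1.11, camera adjusted p = 1.58e-09; adjusted p = 0.343 with an estimated correlation). IRF8 was among the 22 that did not pass over all genes (-0.33 ± 0.27, adjusted p = 0.43). Over 26 myeloid genes, the mean log2 difference from the scramble mean was -0.56 in scramble replicate 3, against 0.396 and 0.163 in the others. The lowest knockdown library was at 0.578. The hairpin 1 mean of 0.94 was 0.61 without its replicate 1. Of 23 NF-kB genes, 10 were higher and 0 lower, and 12 were higher adjusted over the list alone (median 1.00, camera adjusted p = 5.37e-08; adjusted p = 0.231 with an estimated correlation). The survival factor BIRC3 rose by 3.32 ± 0.36 (0.00023), the chemokine CXCL8 by 2.47 ± 0.30 (0.00042) and the NF-kB inhibitor NFKBIA by 1.41 ± 0.18 (0.00056). Lysosome and autophagy genes were higher in 11 of 33 and lower in 0, with 13 higher adjusted over the list alone (median 0.65, camera adjusted p = 4.39e-09; adjusted p = 0.343 with an estimated correlation). The saposin precursor PSAP rose by 1.74 ± 0.35 (0.0072), CTSD by 1.54 ± 0.34 (0.012) and SQSTM1 by 1.11 ± 0.15 (0.00098).

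Growth and amino acid genes fell in MOLM13. The serine synthesis gene PSAT1 fell by 2.13 ± 0.31 (adjusted p = 0.0012) and the one-carbon gene SHMT2 by 1.26 ± 0.18 (0.00096). Of 26 ATF4 and amino acid genes, 17 were lower and 0 higher, and 19 were lower adjusted over the list alone (median -1.23, camera adjusted p = 1.35e-09; adjusted p = 0.343 with an estimated correlation). ODC1, a MYC target of polyamine synthesis, fell by 1.16 ± 0.11 (8.9e-05), and the nucleolar helicase DDX21 by 0.89 ± 0.14 (0.0019). Ribosome biogenesis and MYC targets were lower in 22 of 33 and higher in 0, with 32 lower adjusted over the list alone (median -0.62, camera adjusted p = 1.09e-14; adjusted p = 0.231 with an estimated correlation). Splicing factors were lower in 14 of 42 and higher in 0, with 19 lower and 1 higher adjusted over the list alone (median -0.29, camera adjusted p = 1.27e-06; adjusted p = 0.152 with an estimated correlation). The spliceosome core genes SNRPD1 and SNRPB, whose protein products are arginine-methylated, fell by 1.10 ± 0.15 (0.00097) and 0.83 ± 0.12 (0.0014). Self-renewal genes were lower in 6 of 20, and in 9 adjusted over the list alone (camera adjusted p = 0.00185; adjusted p = 0.152 with an estimated correlation). The survival gene BCL2 fell by 1.31 ± 0.24 (0.0041) and HOXA10 by 0.87 ± 0.24 (0.032). Among p53 targets, 11 of 31 were higher and 0 lower, and 19 were higher and 1 lower adjusted over the list alone (median 0.60, camera adjusted p = 1.07e-06; adjusted p = 0.284 with an estimated correlation). The antiproliferative gene BTG2 rose by 1.62 ± 0.26 (0.0022) and the death receptor TNFRSF10B by 0.72 ± 0.14 (0.0058).

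In all, edgeR called 2760 of 17732 genes in MOLM13, 1149 higher and 1611 lower, of which 680 rose and 592 fell by more than 2-fold. The count was 1045 without scramble replicate 2 and 1149 without scramble replicate 3.

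In MV411 the same question gave fewer genes, with the replication and mitosis genes again lower. CDC45 fell by 3.79 ± 0.30 (SE; adjusted p = 0.00012), the histone chaperone subunit CHAF1B by 3.34 ± 0.25 (0.00012), the mitotic regulator MYBL2 by 3.41 ± 0.33 (0.00041) and AURKB, the kinase of chromosome segregation, by 3.19 ± 0.33 (0.00047). The nucleotide synthesis genes TK1 and RRM2 fell by 3.16 ± 0.33 (0.00047) and 3.10 ± 0.40 (0.0011). Of 49 E2F and DNA replication genes, 47 were lower and 0 higher, and 48 were lower adjusted over the list alone (median -1.91, camera adjusted p = 5.32e-53; adjusted p = 0.162 with an estimated correlation). Mitosis genes were lower in 37 of 38, and in 38 adjusted over the list alone (median -2.20, camera adjusted p = 2.73e-34; adjusted p = 0.272 with an estimated correlation). The proliferation marker MKI67 fell by 2.66 ± 0.33 (0.00097). Scramble replicate 2 stood below the other scramble libraries on both lists, with a mean log2 difference from the scramble mean of -0.602 for E2F genes against 0.325 and 0.277, and of -0.865 for mitosis genes against 0.739 and 0.126. The highest knockdown libraries were at -1.704 and -1.055. Histones were lower in 53 of 57, and in 55 adjusted over the list alone (median -2.04, camera adjusted p = 1.44e-51; adjusted p = 0.162 with an estimated correlation), with the same uncertainty between copies. Amino acid genes were lower in 6 of 26 and higher in 0, with 13 lower adjusted over the list alone (median -0.71, camera adjusted p = 5.47e-09; adjusted p = 0.381 with an estimated correlation). PHGDH, which starts serine synthesis, fell by 1.49 ± 0.26 (0.0058) and the amino acid transporter SLC7A5 by 1.29 ± 0.28 (0.022). For ribosome biogenesis and MYC targets, 0 of 33 passed by edgeR (median -0.35, camera adjusted p = 1.85e-05; adjusted p = 0.618 with an estimated correlation).

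Myeloid, inflammatory and interferon genes were on the higher side in MV411. The growth factor IGF1 rose by 3.62 ± 0.54 (adjusted p = 0.0024), C3 by 3.21 ± 0.67 (0.017) and LGALS3BP, a secreted glycoprotein induced by interferon, by 2.55 ± 0.32 (0.0011). The macrophage marker CD68 rose by 1.51 ± 0.22 (0.0025) and the endotoxin receptor TLR4 by 0.99 ± 0.18 (0.0063). NCF1, a subunit of the phagocyte oxidase, rose by 2.24 ± 0.28 (0.00096), with counts that its pseudogenes make uncertain. Mature myeloid genes were higher in 8 of 34 and lower in 0, with 14 higher adjusted over the list alone (median 0.86, camera adjusted p = 2.89e-08; adjusted p = 0.381 with an estimated correlation). NF-kB genes were higher in 5 of 20 and lower in 0, with 13 higher adjusted over the list alone (median 0.74, camera adjusted p = 1.75e-09; adjusted p = 0.162 with an estimated correlation). BIRC3 rose by 1.99 ± 0.25 (0.001) and the adhesion receptor ICAM1 by 1.29 ± 0.24 (0.0078). Of 37 type I interferon genes, 1 was higher over all genes and 32 were higher adjusted over the list alone (median 1.87, camera adjusted p = 2.12e-12; adjusted p = 0.381 with an estimated correlation). The gene past the threshold was IFIH1, a sensor of double-stranded RNA (1.55 ± 0.27, 0.0062), while IFIT2 (4.18 ± 1.11, 0.051) and MX2 (1.96 ± 0.54, 0.06) did not pass. Lysosome genes were higher in 6 of 33, and in 13 adjusted over the list alone (median 0.56, camera adjusted p = 4.7e-10; adjusted p = 0.381 with an estimated correlation). Targets of p53 were higher in 3 of 32, and in 4 adjusted over the list alone (median 0.30, camera adjusted p = 6.92e-05; adjusted p = 0.381 with an estimated correlation). BTG2 rose by 1.36 ± 0.14 (0.00044).

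EdgeR called 967 of 17816 genes in MV411, 304 higher and 663 lower, of which 159 rose and 468 fell by more than 2-fold. The count was 412 without scramble replicate 1 and 377 without scramble replicate 3. With the hairpins fitted as separate groups it was 2199.

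In SKNO1 few genes passed with both hairpins in the same group. MIDN, which encodes midnolin, a carrier of nuclear proteins to the proteasome, rose by 1.62 ± 0.25 (SE; adjusted p = 0.046) and the histone gene HIST1H2BJ fell by 1.76 ± 0.25 (0.039). RN7SL2, a gene of the signal recognition particle RNA, rose by 0.63 ± 0.10 (0.046), as the share of structured RNAs in these libraries did. CARM1 itself did not pass in this test (-1.80 ± 0.36, adjusted p = 0.07). HBB, the beta globin gene, had 0 counts in the 3 scramble libraries and 142 in the 6 knockdown libraries, at least 26.8-fold higher against a floor of 3 counts over the group. E2F and DNA replication genes had a median of -0.63, with 0 of 49 past over all genes and 27 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.91e-19; adjusted p = 0.506 with an estimated correlation). PRIM1, a primase subunit, was at -0.97 ± 0.17 (0.061) and CHAF1B at -1.06 ± 0.23 (0.086). Mitosis genes had a median of -0.54, with 0 of 38 past over all genes and 10 lower adjusted over the list alone (camera adjusted p = 1.32e-11; adjusted p = 0.506 with an estimated correlation). Lysosome genes had a median of 0.44, with 0 of 33 past and 10 higher adjusted over the list alone (camera adjusted p = 3.02e-05; adjusted p = 0.506 with an estimated correlation). Immediate early genes (median 0.39, camera adjusted p = 0.000738) and mature myeloid genes (median 0.27, camera adjusted p = 0.00696) each had 5 higher members adjusted over the list alone and 0 over all genes, with adjusted p = 0.506 and 0.592 with an estimated correlation. Ribosomal protein genes (median 0.18, camera adjusted p = 7.17e-07) and mitochondrially encoded genes (median 0.38, camera adjusted p = 0.00026) had 0 members past, with adjusted p = 0.515 and 0.531 with an estimated correlation.

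EdgeR called 8 of 18430 genes in SKNO1, 6 higher and 2 lower, while 2779 had an unadjusted p under 0.05. DESeq2 called 690, limma-voom 4, and edgeR 726 with the hairpins as separate groups and 0 with replicate number as a block. The count was 79 without hairpin 1 replicate 2, and 1 without any of scramble replicates 1, 2 and 3 or hairpin 2 replicates 1, 2 and 3.

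**Figure D2:**
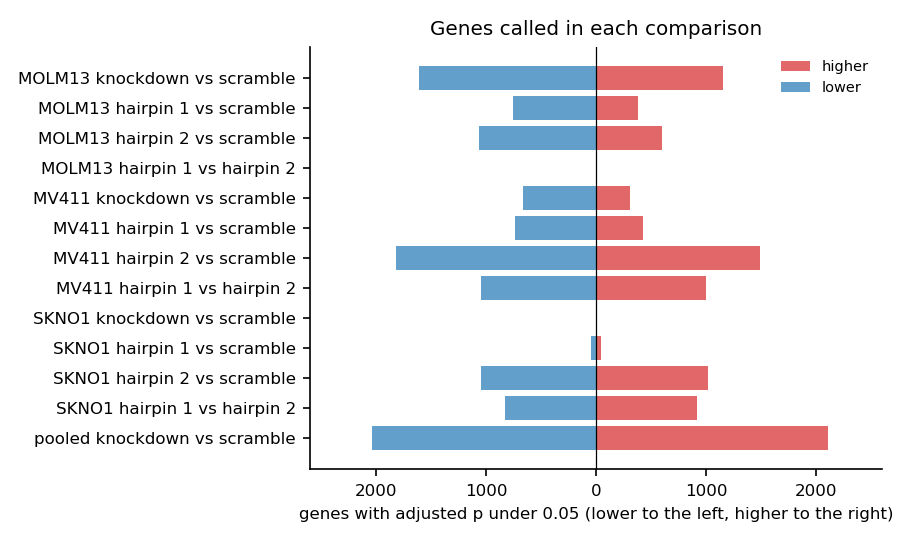
Number of genes with adjusted p under 0.05 in each comparison (horizontal axis, lower to the left and higher to the right). The bars reach 1149 and 1611 in MOLM13, 304 and 663 in MV411, and 6 and 2 in SKNO1.

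All lines were combined to ask what CARM1 loss changes across them. Replication genes fell in the combined data. RFC5, a subunit of the clamp loader, fell by 1.53 ± 0.13 (SE; adjusted p = 1.3e-08), MCM3 by 1.39 ± 0.13 (2.3e-08), CDC45 by 2.49 ± 0.28 (3.7e-07) and XRCC2, a gene of recombination repair, by 2.14 ± 0.19 (1.5e-08). CARM1 fell by 2.21 ± 0.19 (1.5e-08). E2F and DNA replication genes were lower in 48 of 49 both over all genes and adjusted over the list alone (median -1.49, camera adjusted p = 2.99e-51; adjusted p = 0.0877 with an estimated correlation). Mitosis genes were lower in 38 of 38 (median -1.61, camera adjusted p = 1.55e-35; adjusted p = 0.189 with an estimated correlation). The checkpoint genes BUB1B and MAD2L1 fell by 1.77 ± 0.20 (2.9e-07) and 1.64 ± 0.19 (4.1e-07). Histones were lower in 52 of 57, and in 54 adjusted over the list alone (median -1.40, camera adjusted p = 1.84e-32; adjusted p = 0.189 with an estimated correlation).

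Myeloid, NF-kB and lysosome genes rose in the combined comparison. C3 rose by 3.46 ± 0.47 (adjusted p = 4.2e-06), the semaphorin SEMA6B by 2.59 ± 0.36 (6.6e-06) and THBS1, a matrix glycoprotein, by 2.33 ± 0.45 (4e-04). CD68 rose by 1.21 ± 0.17 (7.2e-06), and the myeloid adaptor TYROBP by 1.15 ± 0.17 (1.2e-05). Mature myeloid genes were higher in 22 of 36 and lower in 0, with 24 higher adjusted over the list alone (median 0.63, camera adjusted p = 1e-10; adjusted p = 0.189 with an estimated correlation). NF-kB genes were higher in 13 of 22, and in 16 adjusted over the list alone (median 0.71, camera adjusted p = 1.84e-07; adjusted p = 0.189 with an estimated correlation). ICAM1 rose by 1.31 ± 0.18 (5.5e-06). Lysosome genes were higher in 21 of 33, and in 25 adjusted over the list alone (median 0.47, camera adjusted p = 8.84e-12; adjusted p = 0.189 with an estimated correlation). SQSTM1, the autophagy receptor, rose by 0.84 ± 0.09 (1.8e-07). Targets of p53 were higher in 17 and lower in 1 of 32, and 20 higher and 1 lower adjusted over the list alone (median 0.35, camera adjusted p = 1.72e-06; adjusted p = 0.189 with an estimated correlation). BTG2 rose by 1.33 ± 0.12 (3e-08) and the kinase inhibitor CDKN1A by 1.07 ± 0.22 (0.00079). Type I interferon genes were higher in 8 of 37 on either count and lower in 0 (median 0.58, camera adjusted p = 2.55e-06; adjusted p = 0.415 with an estimated correlation). CXCL10 rose by 2.21 ± 0.51 (0.0026). The rise of the interferon list was not common to the lines or hairpins. Its mean log2 difference from scramble was 2.23 and 1.01 with hairpin 2 in MV411 and SKNO1. With hairpin 1 it was 0.69 and -0.19 there, and in MOLM13 it was 0.07 and -0.14 with hairpins 1 and 2.

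Amino acid genes fell in the combined comparison, as did some cholesterol genes. The asparagine synthetase gene ASNS fell by 1.33 ± 0.19 (adjusted p = 7.6e-06) and the mitochondrial folate gene ALDH1L2 by 1.36 ± 0.19 (7.7e-06), whereas the stress gene NUPR1 rose by 1.19 ± 0.41 (0.035), and by 0.673 (0.449) without the replicates numbered 3. ATF4 and amino acid genes were lower in 17 and higher in 1 of 26, and 20 lower and 1 higher adjusted over the list alone (median -0.58, camera adjusted p = 1.95e-10; adjusted p = 0.189 with an estimated correlation). Cholesterol synthesis genes were lower in 8 of 24, and in 10 adjusted over the list alone (median -0.39, camera adjusted p = 5.48e-05; adjusted p = 0.415 with an estimated correlation). EBP and SQLE fell by 0.70 ± 0.15 (0.0016) and 0.65 ± 0.15 (0.0034). Ribosome biogenesis and MYC targets were lower in 16 of 33, and in 18 adjusted over the list alone (median -0.35, camera adjusted p = 3.14e-09; adjusted p = 0.347 with an estimated correlation). Of the granule genes, the peroxidase gene MPO fell by 0.61 ± 0.22 (0.043), and the granulocyte factor CEBPA rose by 0.41 ± 0.10 (0.0038), with 1 higher and 1 lower of 15 over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.851). BCL2 fell by 1.05 ± 0.20 (0.00033) and the progenitor factor MYB by 0.30 ± 0.08 (0.012). EdgeR called 4149 of 18700 genes, 2108 higher and 2041 lower, of which 396 rose and 432 fell by more than 2-fold. The count was 1624 without the replicates numbered 1, 2336 without those numbered 2 and 2202 without those numbered 3.

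**Figure D3:**
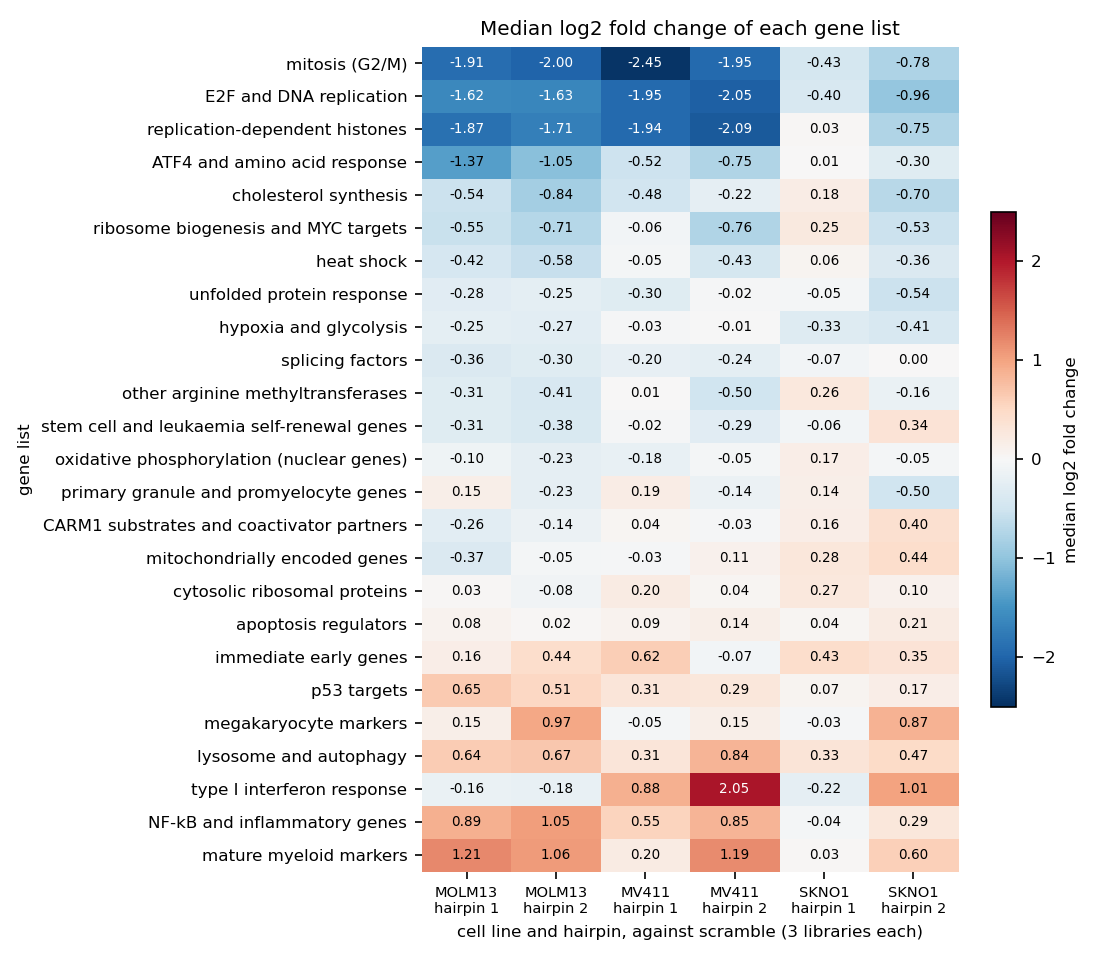
Median log2 fold change of each gene list (vertical axis) for each line and hairpin against scramble (horizontal axis, 3 libraries each). The interferon list reached 2.05 with hairpin 2 in MV411 and 1.01 with hairpin 2 in SKNO1, against 0.88 and -0.22 with hairpin 1.

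The hairpins were compared to ask whether they change the same genes. In MOLM13, hairpin 1 and hairpin 2 called 1131 and 1671 genes. They shared 315 higher genes where 12.8 were expected if independent, 672 lower genes where 45.4 were expected, and 0 genes in opposite directions. In MV411 they called 1159 and 3313 genes and shared 207 higher and 485 lower, against 35.4 and 75.2 expected, with 36 opposite. In SKNO1 they called 98 and 2069 genes and shared 30 higher and 14 lower, against 2.6 and 2.9 expected, with 2 opposite. As both hairpins were set against the same scramble libraries, simulated data without change gave a correlation across genes of 0.50 between them. The observed correlations across genes, which are not independent replicates, were 0.84 in MOLM13, 0.55 in MV411 and 0.42 in SKNO1. The simulated sharing of calls, on data without change, was 0 in each line. The covariance of the fold changes was 0.451 against 0.225 simulated in MOLM13, 0.25 against 0.190 in MV411 and 0.122 against 0.169 in SKNO1. With 3 scramble libraries the controls could not be divided between the hairpins, so the part of these overlaps that the shared controls carry was not measured.

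With hairpin 2 in MV411, interferon and differentiation genes rose while growth genes fell. IFIH1 rose by 1.85 ± 0.22 (SE, n = 3 each; adjusted p = 0.00043), STAT2, a mediator of interferon signals, by 0.98 ± 0.12 (0.00046), and the endosomal RNA sensor TLR8 by 4.77 ± 0.50 (0.00026). Interferon genes were higher in 33 of 37, and in 36 adjusted over the list alone (median 2.05, camera adjusted p = 1.66e-21; adjusted p = 0.203 with an estimated correlation). Mature myeloid genes were higher in 22 of 34, and in 24 adjusted over the list alone (median 1.19, camera adjusted p = 2.32e-15), a call that held with an estimated correlation (adjusted p = 0.0241). CXCL8 rose by 3.05 ± 0.29 (2e-04) and PSAP by 2.34 ± 0.20 (0.00016), with lysosome genes higher in 24 of 33. MYC fell by 1.20 ± 0.12 (0.00025), and ribosome biogenesis and MYC targets were lower in 25 of 33, and in 27 adjusted over the list alone. The neutrophil protease CTSG and the protease inhibitor CST7 fell by 2.02 ± 0.25 (0.00053) and 2.27 ± 0.28 (0.00057), with 6 lower and 2 higher of 15 granule genes on either count. BCL2 fell by 2.15 ± 0.21 (0.00022). The count of 3313 was 1957 without scramble replicate 3 and 1716 without hairpin 2 replicate 1.

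With hairpin 1 in MV411, some immediate early genes rose and interferon genes were higher mainly in replicate 3. JUN rose by 1.95 ± 0.29 (SE, n = 3 each; adjusted p = 0.0043), EGR1 by 1.97 ± 0.30 (0.0047) and KLF2 by 1.90 ± 0.29 (0.0053), with 7 of 20 immediate early genes higher and 8 adjusted over the list alone (camera adjusted p = 2.42e-07; adjusted p = 0.287 with an estimated correlation). DHCR7, the last enzyme of cholesterol synthesis, fell by 1.52 ± 0.22 (0.0041), with 6 of 24 cholesterol genes lower and 11 adjusted over the list alone. BTG2 rose by 1.41 ± 0.14 (0.0015). Mature myeloid genes were higher in 7 and lower in 1 of 34, and 9 higher and 3 lower adjusted over the list alone (median 0.20, camera adjusted p = 0.0028; adjusted p = 0.287 with an estimated correlation). Interferon genes had a median of 0.88 with 1 of 37 higher on either count (camera adjusted p = 2.47e-05; adjusted p = 0.588 with an estimated correlation). The list's mean log2 difference from scramble was 0.060, 0.417 and 1.595 in the 3 libraries, a mean of 0.69 that was 0.24 without replicate 3. The E2F list was lower in 45 of 49 with this hairpin and in 47 with hairpin 2, and in 48 with either adjusted over the list alone. The count of 1159 was 725 without scramble replicate 1, 438 without scramble replicate 3, and 341, 540 and 605 without hairpin 1 replicates 1, 2 and 3.

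With hairpin 2 in SKNO1, interferon genes rose and replication genes fell, while a smaller share of p53 targets and of CARM1 partners passed. OAS1 and OAS3, which sense viral RNA, rose by 3.32 ± 0.36 (SE, n = 3 each; adjusted p = 0.00033) and 2.00 ± 0.24 (0.00065). Interferon genes were higher in 19 of 35, and in 23 adjusted over the list alone (median 1.01, camera adjusted p = 2.09e-13), a call that held with an estimated correlation (adjusted p = 0.0477). CDKN1A rose by 2.14 ± 0.31 (0.0018) and the oxidoreductase gene TP53I3 by 1.71 ± 0.21 (0.00065), with 7 of 29 p53 targets higher, and 10 higher and 1 lower adjusted over the list alone (median 0.17, camera adjusted p = 0.00625; adjusted p = 0.28 with an estimated correlation). The steroid receptor coactivator NCOA3, a CARM1 partner, rose by 1.48 ± 0.23 (0.0028), and 5 of 14 CARM1 substrates and partners were higher, 7 adjusted over the list alone (median 0.40, camera adjusted p = 0.00116; adjusted p = 0.149 with an estimated correlation). E2F and DNA replication genes were lower in 37 and higher in 1 of 49, and 42 lower and 1 higher adjusted over the list alone (median -0.96, camera adjusted p = 1.71e-23; adjusted p = 0.174 with an estimated correlation). ORC1, which marks replication origins, fell by 1.42 ± 0.22 (0.0022). The granule genes MS4A3 and CST7 fell by 2.79 ± 0.36 (0.001) and 2.05 ± 0.38 (0.0062). Cholesterol genes were lower in 11 of 24, and in 18 adjusted over the list alone (camera adjusted p = 1.34e-08; adjusted p = 0.149 with an estimated correlation), with MSMO1 lower by 1.85 ± 0.36 (0.008). Mature myeloid genes were higher in 7 of 28, with TYROBP up by 1.38 ± 0.25 (0.0052). The count of 2069 was 706, 1374 and 1017 without scramble replicates 1, 2 and 3, and 1071, 559 and 769 without hairpin 2 replicates 1, 2 and 3.

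With hairpin 1 in SKNO1, 98 genes passed. BTG2 rose by 1.13 ± 0.17 (SE, n = 3 each; adjusted p = 0.02), and TLR4 fell by 1.03 ± 0.20 (0.044). CARM1 fell by 1.25 ± 0.19 (0.021). E2F and DNA replication genes had 0 of 49 past over all genes and 7 lower adjusted over the list alone (median -0.40, camera adjusted p = 2.45e-07; adjusted p = 0.68 with an estimated correlation). Interferon genes had 0 of 35 past and 2 lower adjusted over the list alone (median -0.22, camera adjusted p = 0.031; adjusted p = 0.68 with an estimated correlation). The count of 98 was 3, 50 and 6 without scramble replicates 1, 2 and 3, and 28, 411 and 6 without hairpin 1 replicates 1, 2 and 3. It was 23, 11 and 15 without hairpin 2 replicates 1, 2 and 3, and DESeq2 gave 973.

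Set directly against each other, the hairpins differed in MV411 and SKNO1. In MV411, PRKAR2B, a regulatory subunit of protein kinase A, was lower with hairpin 1 than with hairpin 2 by 4.16 ± 0.30 (SE, n = 3 each; adjusted p = 7.8e-05), and the kinase gene SGK1 was higher by 2.49 ± 0.47 (0.007). In SKNO1, TP63, a p53 relative, was lower with hairpin 1 by 4.21 ± 0.35 (6.8e-05), and the surface glycoprotein BSG was higher by 2.5 ± 0.19 (3.8e-05). EdgeR called 2046 genes in MV411, 1002 higher and 1044 lower with hairpin 1, and 1754 in SKNO1, 921 higher and 833 lower. Of these, 365 were higher in both lines where 49.7 were expected, 264 were lower in both where 36.2 were expected, and 12 were opposite. In MOLM13 edgeR called 0 genes between the hairpins and DESeq2 1, with 335 at an unadjusted p under 0.05. The MV411 count was 873, 1209 and 1067 without hairpin 1 replicates 1, 2 and 3, and 958 without hairpin 2 replicate 1. The SKNO1 count was 963 without hairpin 1 replicate 3, and 945, 601 and 832 without hairpin 2 replicates 1, 2 and 3. In MOLM13 it was 1 without hairpin 1 replicate 3. For MOLM13 against scramble, the hairpin 1 count was 374 and 335 without scramble replicates 2 and 3, and 577, 390 and 429 without hairpin 1 replicates 1, 2 and 3. The hairpin 2 count was 441 and 482 without scramble replicates 2 and 3, and 1084 without hairpin 1 replicate 2.

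**Figure D4:**
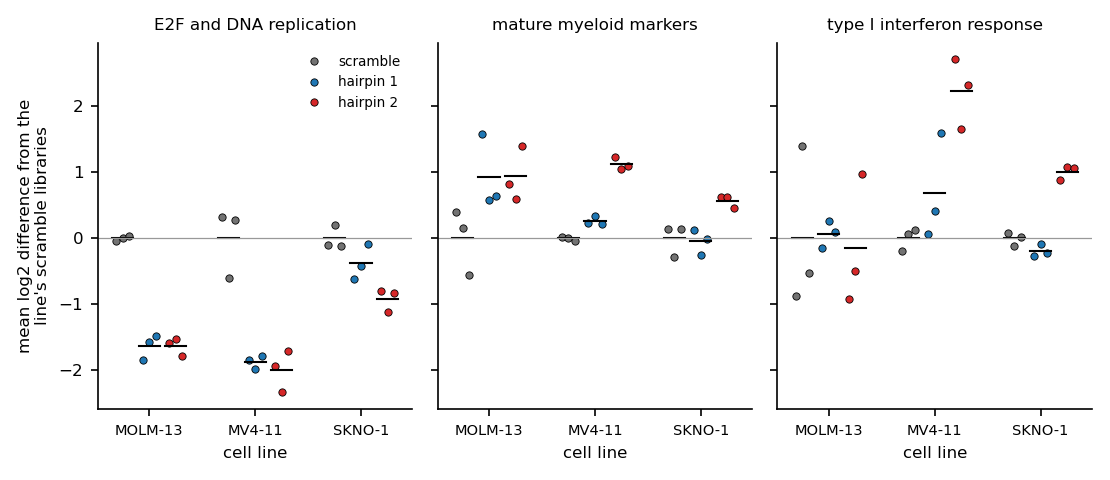
Mean log2 difference of gene lists from the line's scramble libraries (vertical axis) in each library, by line and hairpin (horizontal axis). The E2F list averaged -1.63 with either hairpin in MOLM13, -1.87 and -1.99 with hairpins 1 and 2 in MV411, and -0.37 and -0.91 in SKNO1.

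The lines were compared to ask whether CARM1 loss acts alike in them. MOLM13 and MV411 shared 528 lower genes where 60.5 were expected (Fisher's exact p = 1e-300, the smallest value written) and 168 higher genes where 18 were expected (Fisher's exact p = 4.02e-129), with 1 opposite. The Fisher p-values take genes as independent units, which they are not, and measure no spread between samples. The fold changes of MOLM13 and MV411 correlated across genes with r = 0.726, against 0.354 for MOLM13 and SKNO1 and 0.349 for MV411 and SKNO1. With hairpin 1 these correlations were 0.613, 0.093 and 0.201, and with hairpin 2 they were 0.669, 0.46 and 0.472. SKNO1, with 8 genes called, shared 0 higher and 1 lower with MOLM13 and the same numbers with MV411. With hairpin 1 it shared 6 higher and 6 lower with MOLM13, where 0.849 and 1.95 were expected, and 12 higher and 20 lower with MV411, where 0.988 and 1.93 were expected. With hairpin 2, 293 genes were lower in all 3 lines where 6.55 were expected, and 65 were higher where 2.01 were expected. The knockdown effect itself differed between MOLM13 and SKNO1 for 199 genes, 64 higher and 135 lower in MOLM13. For this pair the count was 1033 with hairpin 1 alone and 65 with hairpin 2 alone, so it depends on the hairpin. BIRC3 differed by 4.22 ± 0.46 (SE; adjusted p = 1.9e-05), with 3.32 in MOLM13 and -0.91 in SKNO1. It differed between MV411 and SKNO1 for 119 genes, 14 higher and 105 lower in MV411, among them the cell cycle genes TCF19 (-3.05 ± 0.44, 0.0017) and MYBL2 (-3.03 ± 0.45, 0.0017). With hairpin 2 both genes were also lower in SKNO1 (-1.043 and -0.840, adjusted p = 0.0087 and 0.0351). That hairpin alone gave 145 genes for MV411 against SKNO1, 60 higher and 85 lower in MV411, of which 44 were among the 119. Between MOLM13 and MV411 edgeR called 0 genes and DESeq2 17, with 947 at an unadjusted p under 0.05. The count for MOLM13 against SKNO1 was 2, 59 and 1 without the replicates numbered 1, 2 and 3. The count for MV411 against SKNO1 was 0 without those numbered 1 and 0 without those numbered 3. Unchanged genes made up 30.9% of calls in the simulated MOLM13 and SKNO1 interaction and 7.8% in that of MV411 and SKNO1. The CARM1 effect did not differ detectably between lines (-0.13 ± 0.49, -0.70 ± 0.49 and -0.56 ± 0.49; adjusted p = 1, 0.53 and 0.74).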

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

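Tests of the hairpin difference by sequence, by weaker knockdown and by a graded response, all tests of HBB, the tests of the E2F list by weaker knockdown and by escaped cells, and the removal of structured RNAs were chosen only after the results were seen. What would count against the last of these was written before it was run.

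The effect of knockdown differed by line for 199 genes between MOLM13 and SKNO1 and for 119 genes between MV411 and SKNO1, which stood out because the hairpins and the harvest time were shared. Between MOLM13 and SKNO1 the count was 1033 with hairpin 1 alone and 65 with hairpin 2 alone. Between MV411 and SKNO1 it was 242 and 145. Against SKNO1, the log2 effect in MOLM13 was larger by 5.61 for the microRNA host gene MIR3142HG (5.82 in MOLM13, 0.23 in SKNO1), by 4.22 for BIRC3 (3.32 and -0.91) and by 3.39 for MERTK, a receptor of phagocytosis (3.77 and 0.38). It differed by -2.51 for the phosphatase gene PTP4A3 (-1.19 and 1.30), by -2.51 for the interferon-induced helicase gene HELZ2 (-0.61 and 1.88) and by -2.46 for the natriuretic peptide receptor NPR3 (-1.41 and 1.03). Of the effects in SKNO1 with both hairpins together, none of these 6 passed the edgeR threshold. With hairpin 2 alone MIR3142HG (0.751), PTP4A3 (1.312), HELZ2 (2.376) and NPR3 (1.341) were higher in SKNO1, and with hairpin 1 alone none of the 6 passed. Without the replicates numbered 2, the difference was 9.050 for MIR3142HG and -1.528 for HELZ2.

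Between MV411 and SKNO1 the effect differed by 4.19 for the zinc finger gene PLAG1, by 2.91 for BIRC3 (1.99 in MV411, -0.91 in SKNO1) and by 2.13 for the phosphodiesterase gene PDE4B (1.82 and -0.30). It differed by -3.30 for GATA2-AS1, by -3.05 for TCF19 (-3.51 and -0.45) and by -3.03 for MYBL2 (-3.41 and -0.37). With hairpin 2 alone TCF19 (-1.043) and MYBL2 (-0.840) were lower in SKNO1, as they were in the other lines, and their difference between the lines passed with that hairpin alone too. Without the replicates numbered 1 the difference was -5.731 for GATA2-AS1. PLAG1 and GATA2-AS1 had too few counts to be tested in SKNO1 and in MV411 respectively, so their values rest on a handful of reads in that line. The drop of the counts when replicates are left out is given with the lines' comparison.

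The hairpins differed from each other in MV411 and SKNO1 and not detectably in MOLM13. In MOLM13 the 607 genes called between hairpins in both other lines scored 0.44 ± 0.40 with hairpin 1 and 0.62 ± 0.36 with hairpin 2 (SD, n = 3), a difference of 0.19 that is within the spread, so an effect of 1 hairpin's sequence in every line cannot be told apart from none. A weaker CARM1 knockdown by hairpin 1 in the other lines stays open. The movement of 0.44 with hairpin 1 in MOLM13, where both hairpins lowered CARM1 alike, rests on replicate 1 at 0.899 and was 0.21 without it. A graded response to the amount of CARM1 left is argued against in SKNO1 for the 1790 genes called in MV411. They scored -0.19 ± 0.09 with hairpin 1, on the other side of scramble from the 0.41 ± 0.03 with hairpin 2. For other genes of SKNO1 it stays open, as the E2F list scored -0.37 ± 0.27 with hairpin 1 and -0.91 ± 0.18 with hairpin 2. In MV411 a graded response stays open. The 1532 genes called in SKNO1 moved there by 0.09 ± 0.05 with hairpin 1, on the same side as the 0.74 ± 0.03 with hairpin 2 but far less. Depth is argued against, since 1961 genes in MV411 and 1749 in SKNO1 were called after every library of the line was thinned to the same total. The share of mitochondrial mRNA in MV411 also differed between the hairpins, and whether library composition carries part of the difference was not tested.

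HBB had 0 counts in the 9 scramble libraries and at least 1 count in 17 of 18 knockdown libraries. Red cell precursor RNA would bring alpha globin, which argues against it in SKNO1 (4 alpha globin counts beside 142 of HBB in 6 knockdown libraries) and in MV411 (2 beside 33). In MOLM13 it cannot be told apart, with 14 beside 28, a share of 33.33% (95% interval 19.57% to 49.55%), and 5 in the scramble libraries beside 0 of HBB. Without hairpin 2 replicate 1, which held 15 of the 28, it was 6 beside 13, a share of 31.58%. A rise with the depth of CARM1 loss is argued against in MV411 by 3 counts with hairpin 2, where less CARM1 was left, beside 30 with hairpin 1, each library being lower. In the other lines it cannot be told apart. In SKNO1 there were 79 with hairpin 2, where less CARM1 was left, and 63 with hairpin 1, and the libraries overlapped. In MOLM13 there were 19 and 9, or 4 and 9 without hairpin 2 replicate 1, and CARM1 did not part the hairpins. Globin sequence carried by the knockdown constructs remains open, as 17 libraries with a count is what it and a response to any CARM1 hairpin would both give, and reads of the constructs were not analysed here. Of all genes, 22 were absent from every scramble library and present in at least 9 of 18 knockdown libraries, with HSPE1P18 next after HBB at 15 libraries.

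E2F and DNA replication genes fell less in SKNO1. A weaker knockdown by hairpin 1 is argued against as the whole cause by a difference of 0.90 between SKNO1 and the other lines with hairpin 2 alone. As a part of the cause it stays open, since the list scored -0.37 ± 0.27 with hairpin 1 and -0.91 ± 0.18 with hairpin 2 in SKNO1. With hairpin 2, cells that escaped the knockdown are argued against by 15.6% of CARM1 left, beside 16.3% in MOLM13. With hairpin 1, which left 42.5% ± 9.18 in SKNO1 (SD, n = 3), escaped cells were not tested and stay open. A distortion of the normalization by structured RNAs is argued against, as the list's median in SKNO1 was -0.61 without them and -0.63 with them. Whether the library composition behind their higher share affects the list was not tested. A difference between the lines stays open and was not tested, and it is confounded with the GM-CSF in the SKNO1 medium and with the low mitochondrial rRNA of that line's libraries. Baseline levels of the list were alike, at 5.02 ± 0.04, 5.01 ± 0.52 and 5.03 ± 0.18 mean log2 CPM in scramble libraries of MOLM13, MV411 and SKNO1 (SD, n = 3).

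For the counts of genes, chance is argued against in MOLM13, where no other split reached the 2760 of the real split (highest other 200). In MV411, 2 of 84 splits called at least 967 genes, a share under 0.05 that was not adjusted over the split tests. Chance was not taken as excluded there. The splits treat the libraries as separate samples, which the labels do not state. In SKNO1 chance was not excluded either. There 4 of 84 splits called at least the 8 genes of the real split, a share just under 0.05 that was not adjusted over the split tests. The SKNO1 count was 0 with replicate number as a block, and 1 when any of the 3 scramble or 3 hairpin 2 libraries was left out. A split that set hairpin 1 replicates 2 and 3 and scramble replicate 2 apart called 227 genes. In MV411 and SKNO1 the highest other splits called 2023 and 1757 genes and were those that set the 3 hairpin 2 libraries apart, so the libraries have a structure in which hairpin 2 stands apart from hairpin 1 and scramble. As such a split also parts hairpin 2 from scramble, it holds a part of the knockdown effect. Chance is also argued against for the combined comparison (4149, highest other 473, 1 of 100 splits), with the same limit on the libraries. The interactions of MOLM13 and MV411 with SKNO1 called 199 genes (highest other 30) and 119 (highest other 8), each with 1 of 100 splits. These splits also break up the knockdown effect within each line, so they cannot decide whether an interaction arose by chance. For MOLM13 against MV411 the real split called 0 genes, which all 100 splits reach by construction, so the splits decide nothing there (highest other 1841). The 10 splits of a hairpin comparison are too few for a share under 0.05. There the real and highest other values were 1131 and 0, and 1671 and 0, in MOLM13 for hairpins 1 and 2, 1159 and 0, and 3313 and 0, in MV411, and 98 and 256 (2 splits), and 2069 and 0, in SKNO1. Between hairpins they were 0 and 193 in MOLM13 (all 10 splits reach 0), 2046 and 0 in MV411 and 1754 and 0 in SKNO1. For the number of gene lists called by camera, 3 of 84 splits reached the 17 of SKNO1 (highest other 19), again without adjustment. Fry and an estimated correlation called 0 lists there, and chance was not taken as excluded. Nor was it in MOLM13 (14, highest other 20, 32 of 84 splits), MV411 (13, highest other 19, 23 of 84 splits) or the combined comparison (17, highest other 20, 10 of 100 splits).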

How the results depend on the processing

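Over 308 pairs of a gene taken by the naming rule and a comparison it passed in, the alternatives gave 4824 values, of which 4358 kept the call and its sign, 465 lost it and 1 reversed (MPO, 0.053 in the combined comparison with no line term). DESeq2 kept 308 of 308, RLE scaling 307, no low count filter 292, and leaving out 1 library or replicate number 1913 of 2183. No line term lost 50 of 86 and reversed 1, and hairpin 1 alone lost 18 of 95. The alternatives for overlaps, each hairpin alone in the interactions and the removal of structured RNAs were added after the data were examined, and that removal moved no count by over 1.5 times. RLE scaling moved none by that much either. The deposited values are counts, so other units were not applicable. The causes of the changes below were not tested.

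DESeq2, for which unchanged genes made up 27.7% of calls in the simulated MOLM13 data against 8.8% by edgeR, gave more genes in MV411 (1773), SKNO1 (690), hairpins 1 and 2 of MOLM13 (2046 and 2749), hairpin 1 of MV411 (1819) and of SKNO1 (973), and between the hairpins of MOLM13 (1). It gave 17, 796 and 403 for the interactions of MOLM13 with MV411, MOLM13 with SKNO1 and MV411 with SKNO1. The simulated share for DESeq2 rests on a single draw with edgeR's spreads and was not obtained outside MOLM13. Without the low count filter, which moved the median log2 fold change of all genes to 0.26 in MOLM13 and 0.15 in the combined comparison, the counts were 107 in SKNO1, 2185 and 2897 for the hairpins of MOLM13, 1913 and 774 for hairpin 1 of MV411 and SKNO1, 59 between the hairpins of MOLM13, and 6 for MOLM13 with MV411. With limma-voom SKNO1 had 4 genes, with a fit over all 27 libraries 231, and with hairpins as separate groups 726, as MV411 had 2199.

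With replicate number as a block, SKNO1 had 0 genes by edgeR, hairpin 1 had 2250 in MV411 and 458 in SKNO1, and 3516 differed between the hairpins of MV411. Libraries of the same number correlated at over 0.1 in 5, 8 and 4 of 9 pairs in MOLM13, MV411 and SKNO1. The lowest correlations were -0.263, 0.064 and -0.086. As not every pair was over 0.1, the main tests did not take the numbers to pair the samples. A pairing was not excluded by this, least of all in MV411. Of 9 libraries in each line, 5, 7 and 7 were closest to another of their own number, a hint of shared handling from the data and not from the labels.

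The combined count was 773 with no line term, 1338 without MOLM13, 2229 without MV411 and 2265 with hairpin 1 alone. With only the 6 libraries compared, it was 1722 for hairpin 1 of MOLM13, 2170 for hairpin 2 of MV411, and 7 and 3305 for hairpins 1 and 2 of SKNO1. With hairpin 1 alone the interactions gave 4, 1033 and 242 genes, and with hairpin 2 alone 10 and 65 for MOLM13 with MV411 and with SKNO1.

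Leaving out 1 library gave 1045 to 3449 genes in MOLM13, 377 to 988 in MV411 and 1 to 79 in SKNO1, and leaving out a replicate number 1624 to 2336 in the combined comparison. For hairpins 1 and 2 it gave 335 to 1436 and 441 to 1774 in MOLM13, 341 to 1562 and 1716 to 3548 in MV411, and 3 to 411 and 559 to 2813 in SKNO1. Between hairpins it gave 0 to 1 in MOLM13, 873 to 2105 in MV411 and 601 to 2178 in SKNO1. Interactions ranged from 1 to 59 for MOLM13 with SKNO1 and from 0 to 125 for MV411 with SKNO1.

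Camera's 14, 13, 17 and 17 list calls in MOLM13, MV411, SKNO1 and the combined comparison became 1, 0, 0 and 0 with an estimated correlation, and with fry 4 in MV411 and 0 in SKNO1. With hairpin 1 alone SKNO1 had 10, and 4 lists reversed there: ribosome biogenesis and MYC targets (adjusted p = 0.00605), interferon (0.031), cholesterol (0.0609) and histones (0.382).

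Genes shared by the hairpins, higher and lower, were 682 and 1020 in MOLM13 by DESeq2, 351 higher in MV411, and 217 and 110 in SKNO1. Without the filter they were 780 higher in MOLM13, 344 and 730 in MV411, and 174 and 134 in SKNO1, and with the block 463 and 837 in MV411, and 112 and 61 in SKNO1. MOLM13 and MV411 shared 436 higher genes by DESeq2. With hairpin 2, all 3 lines shared 146 higher and 477 lower genes by DESeq2, and 165 and 592 without the filter.

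Signs that reversed for genes that had not passed were those of PRMT5 in SKNO1 (-0.010 with limma-voom, -0.011 with separate hairpins), of PRMT1 (0.019), PRMT2 (-0.165), PRMT5 (0.044) and PRMT7 (0.086) combined with hairpin 1 alone, of PRMT7 combined without MV411 (0.046), and of the CARM1 interactions of MOLM13 with MV411 (0.324) and SKNO1 (0.052) with hairpin 2 alone. Leaving out 1 library gave PRMT2 -0.148 to 0.005 in MV411. In SKNO1 it gave PRMT2 -0.001 to 0.176, PRMT3 -0.217 to 0.176, PRMT5 -0.073 to 0.138, PRMT6 -0.090 to 0.168 and PRMT9 -0.017 to 0.150. Leaving out a replicate number gave PRMT7 -0.104 to 0.029 in the combined comparison.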

Other observations

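The readings of the hairpin difference below were chosen only after the results were seen.

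Stress and metabolic genes moved in ways not described above. In MOLM13 the chaperones HSPD1 and HSPH1 fell by 0.85 ± 0.14 (SE; adjusted p = 0.0031) and 0.84 ± 0.15 (0.0039), with 5 of 14 heat shock genes lower over all genes, and 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00361; adjusted p = 0.428 with an estimated correlation). XBP1, which drives the unfolded protein response, fell by 1.07 ± 0.20 (0.0048) and EDEM1 by 1.04 ± 0.19 (0.004), the 2 of 16 genes of that list to pass (camera adjusted p = 0.106). LDHA, the lactate dehydrogenase, fell by 1.02 ± 0.19 (0.0051), while PFKFB3, which speeds glycolysis, rose by 1.03 ± 0.21 (0.0084), with 3 of 28 hypoxia and glycolysis genes higher and 5 lower, and 4 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.106). FDPS fell by 0.99 ± 0.25 (0.022), with 3 of 24 cholesterol genes lower, and 5 adjusted over the list alone (median -0.66; camera adjusted p = 0.000444; adjusted p = 0.6 with an estimated correlation). ZFP36, which destabilises cytokine mRNA, rose by 0.69 ± 0.12 (0.0033), with 8 of 23 immediate early genes higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0706). Nuclear genes of oxidative phosphorylation had 0 of 36 past (median -0.17; camera adjusted p = 0.0312; adjusted p = 0.743 with an estimated correlation).

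Some lists gave mixed signs or little. In MOLM13, 2 interferon genes were higher and 1 lower of 36 on either count, with TRIM22 at 1.10 ± 0.25 (adjusted p = 0.015) and USP18 at -1.45 ± 0.32 (0.013). The list's median was -0.23 and its mean -0.30, while camera's direction was up (adjusted p = 0.275), and scramble replicate 2 alone stood 1.40 above the line's scramble mean. Signs also differed for granule genes in MOLM13 (median 0.04, mean -0.05, camera down, adjusted p = 0.835) and in MV411 (median -0.06, mean 0.05, camera down, adjusted p = 0.92). They differed for hypoxia genes in MV411 (median -0.01, mean 0.16, camera up, adjusted p = 0.92), for splicing factors in SKNO1 (median 0.01, mean -0.02, camera down, adjusted p = 0.837), for B lymphoid markers in the combined comparison (median 0.33, mean -0.10, camera up, adjusted p = 0.997), and for markers of adherent cells in MOLM13 (median 0.06, camera down, adjusted p = 0.963). Of lineage lists, camera gave adjusted p = 0.0706 for megakaryocyte markers in MOLM13 (1 of 8 higher, THBS1 at 2.27 ± 0.39, 0.0033) and 0.127 in the combined comparison (2 of 8 higher). T and NK markers had fewer than 5 tested genes in every line and were not tested by camera. In MOLM13, GNLY of that list rose by 1.37 ± 0.40 (0.038) and CD3D fell by 1.68 ± 0.44 (0.027). Erythroid markers had 1 of 6 higher in SKNO1, which was HBB (camera adjusted p = 0.0315; adjusted p = 0.515 with an estimated correlation). In the combined comparison apoptosis regulators were higher in 5 and lower in 1 of 24, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.059), with BBC3, which promotes apoptosis, up by 0.52 ± 0.15 (0.011).

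CARM1 substrates and partners had 2 of 14 higher and 3 lower in the combined comparison on either count (camera adjusted p = 0.84). NCOA3 rose by 0.66 ± 0.20 (adjusted p = 0.016) and the RNA-binding protein gene ELAVL1 fell by 0.31 ± 0.09 (0.012). In SKNO1 that list had 0 of 14 past by edgeR (median 0.30, camera adjusted p = 0.00696; adjusted p = 0.506 with an estimated correlation). Interferon genes of SKNO1 had 0 of 35 past and 1 higher adjusted over the list alone (median 0.53, camera adjusted p = 0.00737; adjusted p = 0.651 with an estimated correlation), and hypoxia genes 0 of 28 (median -0.31, camera adjusted p = 0.000275; adjusted p = 0.592 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 past in the combined comparison by edgeR (camera adjusted p = 0.566), and ribosomal protein genes had 4 of 75 higher, 1 adjusted over the list alone (camera adjusted p = 0.00136; adjusted p = 0.648 with an estimated correlation).

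A candidate explanation of the myeloid and interferon response to hairpin 2 in MV411 and SKNO1 is a threshold in CARM1, as the amount left was 13.0% and 15.6% with that hairpin and 26.2% and 42.5% with hairpin 1. The genes called between hairpins moved by 0.44 ± 0.40 with hairpin 1 in MOLM13, where 19.4% was left, and by 0.21 without replicate 1, so they do not decide it. Mature myeloid genes scored 0.94 ± 0.57 and 0.94 ± 0.42 with hairpins 1 and 2 in MOLM13 (SD, n = 3 each). In MV411 and SKNO1 they scored 1.13 ± 0.09 and 0.57 ± 0.1 with hairpin 2, and 0.26 ± 0.06 and -0.04 ± 0.19 with hairpin 1. The MOLM13 values of that list go with a threshold, although the line's scramble libraries spread by 0.5. They do not part a threshold from a graded response. Interferon genes give a threshold no support in MOLM13. They scored 0.07 ± 0.21 with hairpin 1 and -0.14 ± 1.00 with hairpin 2 (SD, n = 3) at 19.4% and 16.3% of CARM1. The hairpin 2 value there was -0.7 without replicate 3 and 0.25 without replicate 1. In MV411 the score with hairpin 1 was 0.69 ± 0.80, and its highest library, at 1.595, was near the lowest with hairpin 2, at 1.661. Their mean of -0.03 over the 6 knockdown libraries leaves a threshold open for that list, as the scramble libraries of the line spread by 1.22. The value of -0.19 in SKNO1 argues against a graded response there for the 1790 genes called in MV411. It does not do so for other genes. The E2F list scored -0.37 ± 0.27 with hairpin 1 and -0.91 ± 0.18 with hairpin 2 in SKNO1. In MV411 the 1532 genes called in SKNO1 scored 0.09 ± 0.05 with hairpin 1, on the side of hairpin 2 but small beside its 0.74 ± 0.03. That shared sign alone does not decide for a graded response. An effect of either hairpin on other targets was not excluded by the difference of 0.19. Interferon genes are also induced by double-stranded RNA, which was not measured here. A cell line expressing a hairpin-resistant CARM1 would part effects of CARM1 loss from those on other targets, but not a threshold from a graded response.

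The loss of replication, mitosis and histone genes with a rise of p53 targets and of myeloid genes could come from fewer cycling cells, from differentiation or from both, and bulk RNA does not part them. In SKNO1 the fall was smaller, by 0.90 with hairpin 2, while interferon genes rose with that hairpin. Cell cycle profiles and surface markers of the same cultures would decide.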
